A study of Homo sapiens with 30 samples.

How the data were processed

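PC3 cells were treated for 48 h with DMSO, SGI-1776 at 1500 or 3750 nM, or SGI-1776-VHL-02 at 1500 or 3750 nM, and 30 libraries were sequenced, 6 per group. Per the labels, total RNA was extracted with an RNeasy kit and messenger RNA was purified on poly-T beads, fragmented and copied into cDNA with random hexamers. The labels name second-strand synthesis with dUTP or with dTTP as alternatives and do not say which was used, so the strand setting of the counting is unknown. The authors counted reads per gene with featureCounts 1.5.0-p3 on GRCh38/hg38, and the aligner is not given in the sources used here. The deposited table holds raw counts without normalization for 58735 genes, 1 column per library, with gene names, coordinates and gene length in bases. All 58735 gene identifiers were found in GENCODE 29 with the same chromosome, start and end. Totals ran from 22520292 to 48968707 counts per library, and 20677 genes had no count in any library. Counts of reads without molecular identifiers are not independent molecules, and the standard errors given are those of the fitted model.

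Each library was assigned to its group by its label, and the labels also number the libraries of a group as Rep 1 or Rep 2 and, in brackets, as 1 to 3. The labels do not say which libraries come from separate cultures. The p-values therefore measure the spread between these libraries, which can in part be technical. The Rep numbers paired the groups, because the difference between Rep 2 and Rep 1 correlated between all 10 pairs of groups (across genes, Pearson 0.507 to 0.672). Within groups, libraries of other groups with the same Rep number correlated at 0.207 on average and those with the other number at -0.206, and the first axis held 35.8% of the variance. Bracketed numbers paired them hardly at all (0.0395 for the same number and -0.0196 for another). No pair of libraries was a copy of another.

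Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (17499 genes), scaled by TMM (trimmed mean of M-values), and fitted with a quasi-likelihood model of the 5 groups over all 30 libraries. Each contrast was tested two-sided, with Benjamini-Hochberg adjustment over the 17499 genes and a threshold of 0.05. The 9 contrasts were each treatment against DMSO, the 2 compounds at the same dose, the 2 doses of each compound, and the interaction, which is the compound difference at 3750 nM less that at 1500 nM. A gene rose, fell or changed where it passed this threshold. CPM is a count scaled to the library size after TMM, as given by edgeR. Values are log2 fold changes with the standard error (SE), taken as the size of the log2 fold change over the root of its F statistic. Beside each count of genes stands the count after the 3 libraries of each group and Rep were summed, which leaves 2 samples per group.

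To group genes, 33 lists were fixed: PIM kinases, other reported SGI-1776 targets, VHL ubiquitin ligase, hypoxia and HIF targets, MYC targets, G1/S and DNA replication, G2/M and mitosis, p53 targets, NRF2 targets, ATF4 and amino acid stress, ER chaperones, cholesterol synthesis, fatty acid synthesis, lysosome, autophagy, interferon response, NF-kB and cytokines, BCL2 family, MAPK and immediate early genes, FOXO and PI3K targets, EMT and extracellular matrix, ribosomal proteins, nuclear respiratory chain, mitochondrially encoded genes, aryl hydrocarbon receptor targets, proteasome, heat shock, metallothioneins, glycolysis, neuroendocrine markers, luminal and androgen receptor markers, leukocyte markers, and fibroblast and endothelial markers. The 32 lists with at least 3 tested members were tested with camera from limma 3.58.1 at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera compares a list with the other genes. The same test with the correlation estimated from the residuals and fry, a test of whether a list's members move on balance 1 way, were run beside it. Members are counted as passing over all genes tested and when adjusted over the list alone.

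Named genes followed a rule. PIM1, PIM2, PIM3 and VHL were always given. In each contrast with DMSO or between compounds, the 6 protein-coding genes with the highest and the 6 with the lowest log2 fold change were named among those called in the 30-library fit and in the fit summed per Rep, with the same direction in both Reps and a mean of at least 5 CPM in 1 of the groups. The dose contrasts and the interaction name 4 in each direction. Some genes that meet this rule are not reported here. Up to 4 members of a passing list, and up to 2 of another, were named from those called in both fits. In SGI-1776 1500 nM and SGI-1776-VHL-02 1500 nM against DMSO, in the 2 doses of SGI-1776 and in the interaction, the summed fit called no gene, and the fit summed per Rep with Rep as a block took its place, a change made after the counts were seen. Gene lists, contrasts, thresholds, this rule and most alternatives were chosen before the data were examined.

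Across genes, fold changes of 2 contrasts were compared by Pearson and Spearman correlation and covariance. Contrasts that share the DMSO libraries correlate without any treatment effect, so 20 simulations of unchanged groups and 20 splits of the DMSO libraries into 3 and 3 were run beside them. Genes are not independent replicates. The distance of a library was the root mean square difference of its log2 CPM from the DMSO mean, and a DMSO library was compared with the mean of the other DMSO libraries. Groups were compared on it with an exact two-sided permutation test of 6 against 6 libraries (924 arrangements, smallest possible p = 0.00216), adjusted over 8 comparisons.

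Alternatives were DESeq2 1.42.0, RLE factors or library size only in place of TMM, no filter or a mean of at least 1 CPM, Rep or the bracketed number as a block, and libraries summed per Rep or per bracketed number. Others were limma voom with the libraries of a group and Rep as a correlated set (correlation 0.371), a fit of only the groups compared, a 2-fold threshold, glmTreat at a fold of 1.2, and each library or Rep left out. Chosen after the data were seen were robust edgeR, log2 of the mitochondrial share of counts as a covariate with and without Rep as a block, leaving out 4 libraries with under 0.5% mitochondrial counts, camera with Rep as a block and an estimated correlation, and a list of histone genes.

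The tests were checked on simulated data in which genes of the SGI-1776-VHL-02 3750 nM contrast were changed by known folds. The 30-library fit recovered 52%, 86%, 96% and 100% of genes changed 1.25, 1.5, 2 and 4-fold, and 3.47% of its calls were unchanged genes. With Rep as a block these were 68%, 90%, 98% and 100%, with 8.25%. Summed per Rep they were 10%, 54%, 72% and 94%, with 0%. Summed per Rep with Rep as a block, the fit used to name genes in 4 contrasts, they were 62%, 84%, 100% and 100%, with 10.4%. For lists, camera called 30 genes raised 1.25-fold in the SGI-1776 3750 nM contrast and did not call 30 unchanged genes. Apart from a shift between Reps the genes were simulated independently. The check therefore cannot show how the preset correlation serves lists whose genes move together. Libraries were drawn independently too, apart from that shift. The shares of false calls thus do not cover the case that libraries of a group and Rep share a culture. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9. Protein levels were not measured, and no data beyond the deposited counts were used here.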

Results

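Gene expression was measured by poly-A RNA sequencing in PC3 cells, a human prostate cancer line that lacks functional p53, after 48 h of treatment. SGI-1776 is a small-molecule inhibitor of the PIM kinases, a family of serine/threonine kinases that promote survival and growth. SGI-1776-VHL-02 is a PROTAC, a molecule made to bring its target to a ubiquitin ligase for degradation. The question was how the transcriptome responds to a PIM kinase inhibitor and to a PROTAC made to degrade these kinases. The 5 groups were DMSO (the solvent), SGI-1776 at 1500 and 3750 nM, and SGI-1776-VHL-02 at 1500 and 3750 nM, each with 6 libraries of 22520292 to 48968707 counts. Of 58735 genes, 17499 were tested. Within every group the libraries of Rep 2 held a lower share of mitochondrially encoded counts (0.296 to 1.67%) than those of Rep 1 (1.94 to 3.96%).

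**Figure D1:**
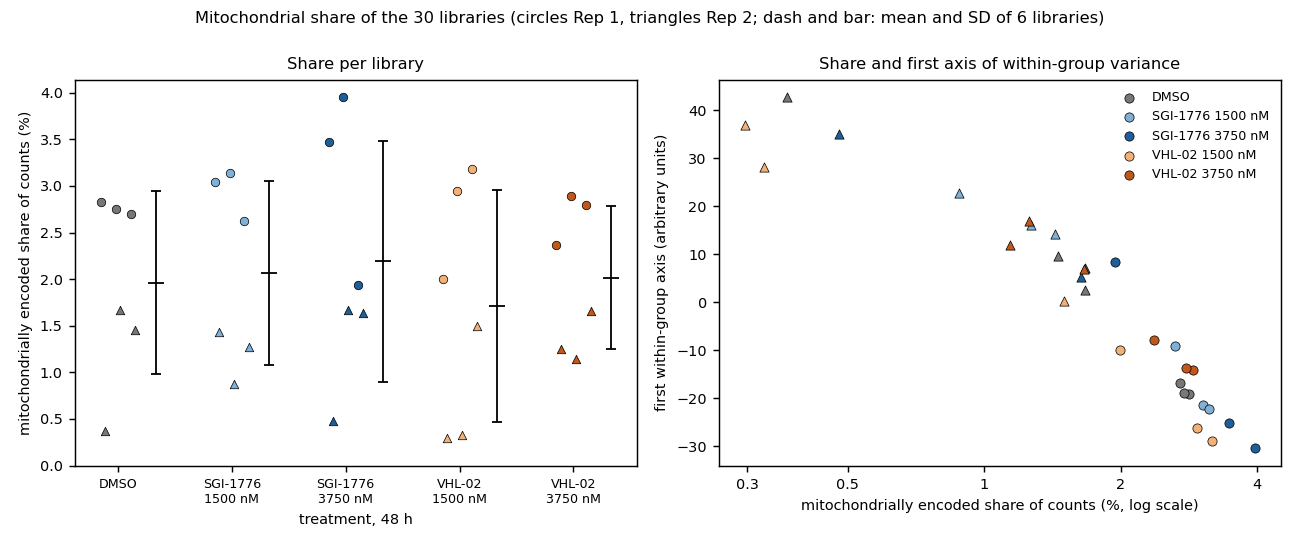
Mitochondrially encoded share of counts (%) of the 30 libraries by treatment (left) and against the first axis of within-group variance in arbitrary units (right, log scale for the share), with circles for Rep 1, triangles for Rep 2, and dash and bar for mean and SD of 6 libraries. The mean share was 2.84% in Rep 1 and 1.13% in Rep 2, and the first axis held 35.8% of the within-group variance.

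To place the drug targets themselves, the PIM genes and VHL were compared first. PIM1 encodes a kinase that is itself induced by cytokine and JAK/STAT signalling, and VHL encodes the substrate receptor of the ubiquitin ligase for which the PROTAC is named. PIM1 mRNA rose with either compound at the higher dose, and with SGI-1776 at the lower dose as well. PIM2 and PIM3 changed in none of the 9 contrasts, while VHL rose with the PROTAC at the higher dose. PIM1 (ENSG00000137193, chromosome 6, 37170203 to 37175426) averaged 30.7 ± 1.24 CPM (SD, n = 6) in DMSO, 35.3 ± 2.41 and 44.2 ± 1.46 with 1500 and 3750 nM SGI-1776, and 33.3 ± 0.814 and 41.1 ± 3.06 with 1500 and 3750 nM PROTAC. Its log2 fold change against DMSO was 0.53 ± 0.05 (SE, adjusted p = 1.61e-10) with 3750 nM SGI-1776 and 0.42 ± 0.05 (adjusted p = 2.31e-08) with 3750 nM PROTAC, and both passed with libraries summed per Rep. At 1500 nM it was 0.20 ± 0.05 with SGI-1776 (adjusted p = 0.00279, and 0.411 summed per Rep) and 0.12 ± 0.05 with the PROTAC (adjusted p = 0.188, 95% interval 0.02 to 0.21). The 2 compounds did not differ on PIM1 at 1500 nM (log2 difference -0.08, 95% interval -0.18 to 0.01, adjusted p = 0.178). At 3750 nM the difference was -0.11 (95% interval -0.20 to -0.01, adjusted p = 0.0711), and it passed with Rep as a block (adjusted p = 0.0347). VHL (ENSG00000134086, chromosome 3, 10141008 to 10152220) rose by 0.16 ± 0.04 with 3750 nM PROTAC against DMSO (adjusted p = 0.00279) and was 0.16 ± 0.04 higher than with 3750 nM SGI-1776 (adjusted p = 0.00217). Neither passed when libraries were summed per Rep (adjusted p = 0.381 and 0.293). PIM2 (ENSG00000102096, chromosome X, 48913182 to 48919024) averaged 27.8 ± 1.03 CPM in DMSO, and PIM3 (ENSG00000198355, chromosome 22, 49960513 to 49964080) averaged 52.7 CPM. Of the genes listed as other SGI-1776 targets, the mitotic kinase gene HASPIN was the 1 member tested, and it fell with SGI-1776 at 1500 nM (-0.29 ± 0.07, adjusted p = 0.00359) and 3750 nM (-0.48 ± 0.07, adjusted p = 1.99e-06).

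**Figure D2:**
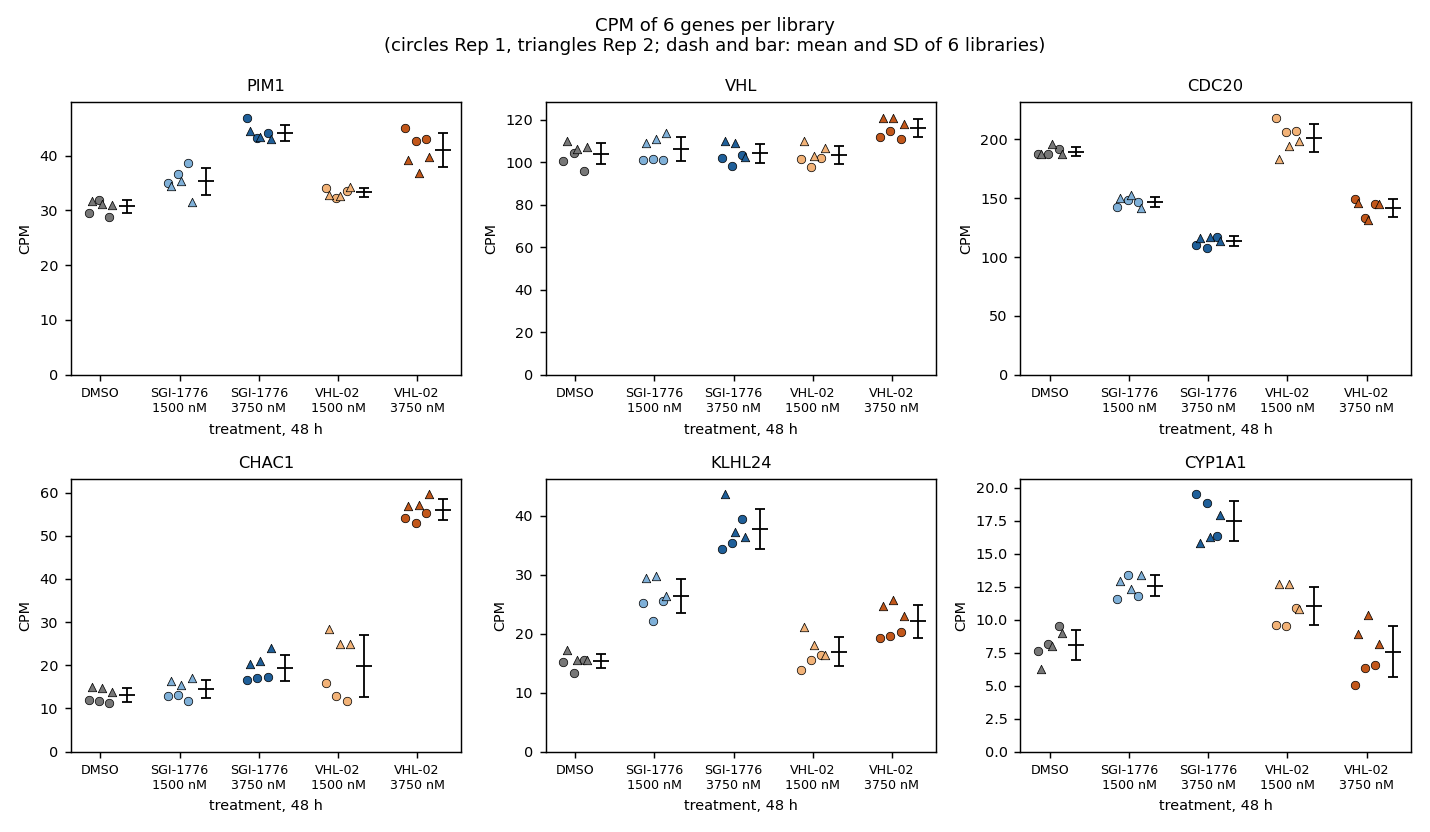
CPM of PIM1, VHL, CDC20, CHAC1, KLHL24 and CYP1A1 in each library (vertical axis) by treatment for 48 h, with circles for Rep 1, triangles for Rep 2, and dash and bar for mean and SD of 6 libraries. CHAC1 averaged 13.1 CPM in DMSO, 19.3 with 3750 nM SGI-1776 and 56.0 with 3750 nM PROTAC, and CDC20 averaged 190 CPM in DMSO, 114 with 3750 nM SGI-1776 and 201 with 1500 nM PROTAC.

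To find what inhibition at the lower dose changed, SGI-1776 at 1500 nM was compared with DMSO. Genes that carry cells through division fell, among them CDC20, an activator of the complex that ends mitosis, and the mitotic kinase gene PLK1. Targets of FOXO factors, which are active when PI3K and AKT signalling is low, rose, with KLHL24, SESN3 and BCL6. INSIG1, which answers to the sterol-regulated SREBP factors, rose as well. In the NF-kB list of inflammatory genes 9 of 25 fell, IL1B and CXCL1 among them, and the list did not hold (adjusted p = 0.341 with an estimated correlation).

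Among genes called both in the 30-library fit and in the fit summed per Rep with Rep as a block, those with the highest fold changes included KLHL24 (ENSG00000114796, chromosome 3, 183635568 to 183684477; log2 fold change 0.78 ± 0.09, adjusted p = 6.65e-07), TP53INP1 (0.74), CEMIP (0.72), SLC4A4 (0.71) and LAMA4 (0.71). Those with the lowest included SERF1B (-1.25 ± 0.40), EIF3C (-0.92 ± 0.24), CPA4 (-0.73), ESM1 (-0.72) and LRRC38 (-0.71). SERF1B and EIF3C have near-identical copies in the genome, so their counts are uncertain. None of these 10 genes passed when libraries were summed per Rep without the block. Of 30 mitosis genes 26 fell and none rose (29 adjusted over the list alone, median -0.21, adjusted p = 3.23e-29), with CDC20 at -0.37 ± 0.04 and PLK1 at -0.32 ± 0.04. Of 32 MYC targets 18 fell (24 adjusted over the list alone, adjusted p = 2.19e-13), LYAR and BOP1 among them, and of 23 FOXO targets 15 rose and GADD45A fell (17 and 1 adjusted over the list alone, adjusted p = 1.1e-11). These 3 lists also passed with an estimated correlation (adjusted p = 0.00189, 0.00715 and 0.00111). Of 32 G1/S genes 21 fell, including CDT1 and TYMS (27 adjusted over the list alone, adjusted p = 1.11e-17, but adjusted p = 0.0667 with an estimated correlation). Of 31 proteasome genes 16 fell, including PSMD2 (22 adjusted over the list alone, adjusted p = 5.02e-11, but adjusted p = 0.204 with an estimated correlation). In the cholesterol list 5 of 25 genes rose (11 adjusted over the list alone, adjusted p = 1.65e-05, but adjusted p = 0.472 with an estimated correlation). In the NF-kB list 9 of 25 fell (12 adjusted over the list alone, adjusted p = 4.96e-05, but adjusted p = 0.341 with an estimated correlation). The EMT, glycolysis, respiratory chain, VHL ligase and heat shock lists passed downward, and the aryl hydrocarbon receptor, lysosome, autophagy and fatty acid lists passed upward. None of these 9 held (adjusted p = 0.0667 to 0.472 with an estimated correlation). With Rep as a block besides, G1/S, proteasome, cholesterol and autophagy genes passed with an estimated correlation too (adjusted p = 0.0166, 0.0393, 0.0208 and 0.0266).

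In all, 2263 genes changed, 924 higher and 1339 lower, and 12 and 7 of them changed at least 2-fold. With library size only as the scaling, 1322 were higher and 896 lower. Rep as a block gave 3772 genes. Summed per Rep, edgeR called 0 genes, with 1661 at an unadjusted p under 0.05 and 2303 with Rep as a block. DESeq2 on 30 libraries called 2416 and voom with correlated sets 541. Without all of Rep 2 the count was 1097.

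To see the response at the higher dose, SGI-1776 at 3750 nM was compared with DMSO. Mitosis, DNA replication and MYC target genes fell, and at this dose further than at 1500 nM for 28 of 30, 22 of 32 and 8 of 32 of them. Of 25 cholesterol genes 24 rose, a list that passed with an estimated correlation only where Rep was a block (adjusted p = 2.98e-04). Lysosomal genes also rose, among them TPP1 and GPNMB, a glycoprotein of lysosomes and melanosomes. BMF, a BCL2 relative that promotes cell death, rose and BCL2A1, a relative that opposes it, fell, but the BCL2 family list did not pass. The xenobiotic enzymes CYP1A1 and CYP1B1 rose, and so did FOLH1 and ACPP, genes of differentiated prostate epithelium. Neither of their lists held (adjusted p = 0.111 and 0.234 with an estimated correlation), and 3 of 11 luminal markers fell. Where Rep was a block besides, the aryl hydrocarbon receptor list of CYP1A1 did pass with an estimated correlation.

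Among genes also called when libraries were summed per Rep, those with the highest fold changes included CADM2 (ENSG00000175161, chromosome 3, 84958981 to 86074429; 1.75 ± 0.15, adjusted p = 1.75e-10), TDRD6 (1.65), LAMA4 (1.41), CDH12 (1.36) and LRMDA (1.35). Those with the lowest included SERF1B (-2.06), TNC (-1.22 ± 0.10, adjusted p = 7.6e-11), CPA4 (-1.14), ESM1 (-1.13) and EIF3C (-1.09). Of 30 mitosis genes 29 fell (30 adjusted over the list alone, median -0.46, adjusted p = 7.6e-44), of 32 G1/S genes 30 fell (30 adjusted over the list alone, adjusted p = 1.3e-23), and of 32 MYC targets 26 fell (27 adjusted over the list alone, adjusted p = 4e-13). CDC20 fell by 0.74, CDC45 by 0.56 and NME1 by 0.45. Of 23 FOXO targets 19 rose and 1 fell (19 and 1 adjusted over the list alone, adjusted p = 4e-13), including KLHL24 (1.30 ± 0.09) and PIK3IP1 (1.10 ± 0.11). Of 31 lysosomal genes 18 rose and 2 fell (20 and 3 adjusted over the list alone, adjusted p = 2.75e-12), with TPP1 at 0.96 ± 0.05 and CTSB at -0.38 ± 0.03. Of 34 EMT and matrix genes 18 fell and 4 rose (20 and 4 adjusted over the list alone, adjusted p = 1.62e-05). All 6 of these lists passed with an estimated correlation (adjusted p = 0.000253, 0.0236, 0.00842, 0.000253, 0.0398 and 0.0398 in that order), but the EMT list did not with Rep as a block besides (adjusted p = 0.122).

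Cholesterol synthesis genes rose in 24 of 25 cases (24 adjusted over the list alone, median 0.56, adjusted p = 9.79e-16, but not with an estimated correlation), TM7SF2 (0.78) and DHCR7 (0.60) among them. Of 31 proteasome genes 26 fell (27 adjusted over the list alone, adjusted p = 5.73e-11). Neither of these, nor autophagy, fatty acid and ATF4 genes, which passed upward, nor NF-kB and respiratory chain genes, which passed downward, held (adjusted p = 0.111 to 0.576 with an estimated correlation). Of 18 glycolysis genes 13 fell and 1 rose (13 and 2 adjusted over the list alone, adjusted p = 1.19e-07, but adjusted p = 0.111 with an estimated correlation). Of 21 heat shock genes 13 fell and 2 rose (13 and 2 adjusted over the list alone, adjusted p = 2.68e-05, but adjusted p = 0.111 with an estimated correlation), with HSPA6 higher by 0.70. Of 40 ribosomal protein genes 24 rose and 1 fell (28 and 1 adjusted over the list alone, adjusted p = 0.000119, but adjusted p = 0.467 with an estimated correlation). Of 9 aryl hydrocarbon receptor targets 5 rose and 1 fell (5 and 2 adjusted over the list alone, adjusted p = 0.000853, but adjusted p = 0.111 with an estimated correlation), with CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610) at 1.11 ± 0.12. Of 11 luminal and androgen receptor markers 6 rose and 3 fell (7 and 3 adjusted over the list alone, adjusted p = 0.0400, but 0.0807 with Rep as a block and adjusted p = 0.234 with an estimated correlation). The VHL ligase list missed the threshold (adjusted p = 0.0603, but 0.0394 with Rep as a block). With Rep as a block and an estimated correlation together, proteasome, glycolysis, AhR, autophagy and fatty acid lists passed (adjusted p = 0.0339, 0.0287, 0.0447, 0.00241 and 0.0287). In the BCL2 family BMF rose by 1.24 ± 0.07 and BCL2A1 fell by 1.43, while the list did not pass (adjusted p = 0.633). The 24 p53 targets did not pass either (7 rose, 6 fell, adjusted p = 0.633), although GDF15 (1.24) and TP53INP1 rose, and their median (-0.01) and mean (0.11) had opposite signs.

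In all, 6233 genes changed, 3016 higher and 3217 lower, with 178 at least 2-fold higher and 42 at least 2-fold lower. Library size only gave 3737 higher and 2623 lower, and libraries summed per Rep gave 1742 genes. Between the doses of SGI-1776, 780 genes were higher and 821 lower at 3750 than at 1500 nM. Of those that also passed summed per Rep with Rep as a block, the furthest higher were MAGED4 (1.85 ± 0.60, a gene with a near-identical copy), CADM2 (0.86 ± 0.14), LRMDA (0.79) and AQP3 (0.74), and the furthest lower were TNC (-0.61 ± 0.10), COL6A3 (-0.57 ± 0.07), HLX (-0.49) and GBX2 (-0.47). Of 30 mitosis genes 28 were lower at the higher dose (29 adjusted over the list alone, median -0.26, adjusted p = 1.3e-41) and of 31 lysosomal genes 15 were higher and 1 lower (19 and 1 adjusted over the list alone, adjusted p = 9.52e-23), both also with an estimated correlation (adjusted p = 0.00052 and 0.00348). Of 32 G1/S genes 22 were lower (24 adjusted over the list alone, adjusted p = 2.08e-20) and of 32 MYC targets 8 (11 adjusted over the list alone, adjusted p = 7.25e-08), both with an estimated correlation (adjusted p = 0.0443 each), but MYC targets not with Rep as a block besides (adjusted p = 0.0868). Cholesterol genes were higher in 17 of 25 cases (22 adjusted over the list alone, adjusted p = 2.88e-24, but adjusted p = 0.0591 with an estimated correlation, and 2.09e-05 with Rep as a block besides). The PIM kinase list passed on PIM1 alone (0.32 ± 0.04, list adjusted p = 0.0472, 0.0691 with Rep as a block and adjusted p = 0.112 with an estimated correlation). Between doses 1601 genes differed, 3028 with Rep as a block. Summed per Rep, edgeR called 0 genes, with 1343 at an unadjusted p under 0.05 and 1654 with Rep as a block. DESeq2 called 1834 and voom with correlated sets 327.

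**Figure D3:**
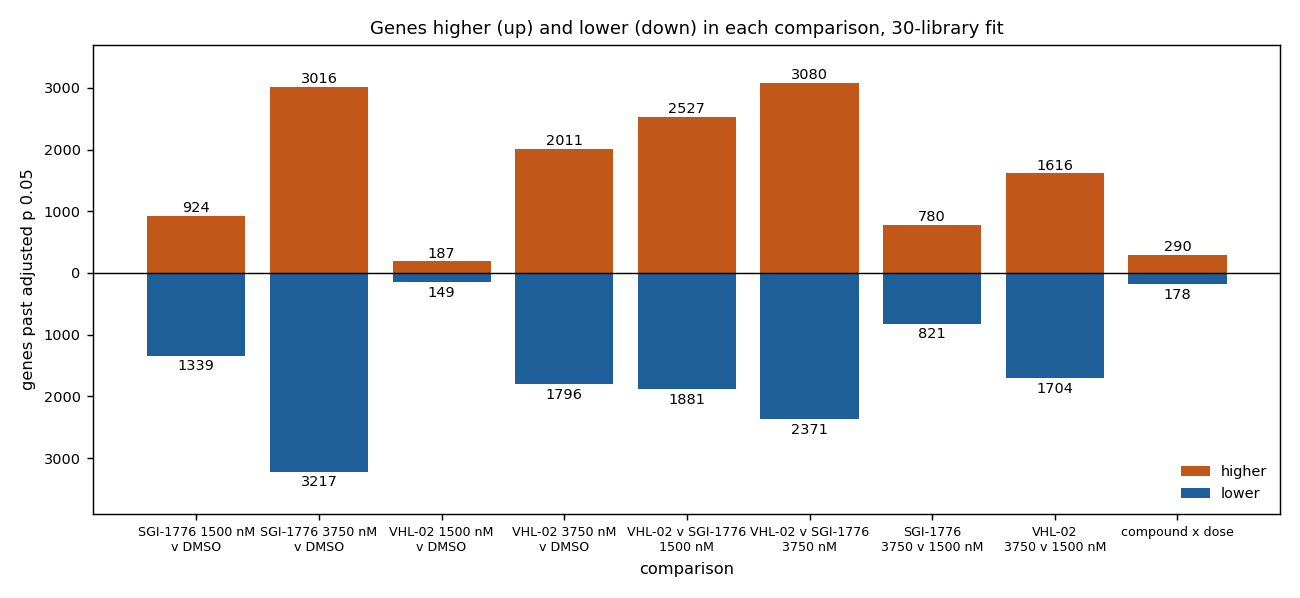
Genes past an adjusted p of 0.05 in each of the 9 comparisons (horizontal axis) in the 30-library fit, with the number higher above 0 and the number lower below it. The counts ran from 336 genes (187 higher, 149 lower) for 1500 nM PROTAC against DMSO to 6233 genes (3016 higher, 3217 lower) for 3750 nM SGI-1776 against DMSO.

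To ask what the PROTAC changed at the lower dose, SGI-1776-VHL-02 at 1500 nM was compared with DMSO. Of 30 genes of the amino acid stress response driven by ATF4, 12 rose, among them CTH, TRIB3 and CHAC1, which degrades glutathione. Of 30 mitosis genes 4 rose slightly, among them TOP2A and CDK1, which had fallen with the inhibitor. Neither list held (adjusted p = 0.264 each with an estimated correlation). The epidermal growth factor relatives AREG and EPGN rose, and SPARC, MMP13 and CTGF, genes of the extracellular matrix and its turnover, fell. They were 3 of the 5 that fell among 34 EMT and matrix genes, a list that did not hold (adjusted p = 0.32 with an estimated correlation). IL33, an alarm cytokine, rose.

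Of the genes that passed with 30 libraries and again summed per Rep with Rep as a block, the highest fold changes were those of IL33 (ENSG00000137033, chromosome 9, 6215786 to 6257983; 0.90 ± 0.15, adjusted p = 0.000543), FGFBP1 (0.77), EPGN (0.69 ± 0.09, adjusted p = 1.79e-05), FER1L6 (0.65), ALPP (0.62 ± 0.07) and CHAC1 (0.60 ± 0.16, adjusted p = 0.0384). The lowest were those of PPP1R1B (ENSG00000131771, chromosome 17, 39626740 to 39636626; -0.88 ± 0.09, adjusted p = 5.61e-07), FCGR2A (-0.84), GBP4 (-0.78), SPARC (-0.76 ± 0.12), CLCN1 (-0.72) and MMP13 (-0.69), and none of these 12 passed when summed per Rep without the block. Of 30 ATF4 and amino acid stress genes 12 rose (21 adjusted over the list alone, median 0.21, adjusted p = 4.29e-15, but adjusted p = 0.264 with an estimated correlation). Without the 4 libraries of under 0.5% mitochondrial counts, 2 of them in this group, 3 of these genes rose (median 0.14, adjusted p = 4.60e-08). The median of this list was 0.13 in Rep 1 and 0.27 in Rep 2, and CHAC1 stood at 0.21 and 0.84. In this group Rep 2 had a mean mitochondrial share of 0.707% against 1.16% in DMSO. Of 30 mitosis genes 4 rose, 3 without these libraries (15 adjusted over the list alone, median 0.12, adjusted p = 6.23e-12, but adjusted p = 0.264 with an estimated correlation). Of 22 ER chaperones 4 rose, including DNAJB9 (6 adjusted over the list alone, adjusted p = 1e-06, but adjusted p = 0.56 with an estimated correlation), and of 27 NRF2 targets HMOX1, FTH1 and TXN rose (4 adjusted over the list alone, adjusted p = 0.00146, but adjusted p = 0.56 with an estimated correlation). Of 34 EMT genes 5 fell (7 fell and 3 rose adjusted over the list alone, adjusted p = 0.00146, but adjusted p = 0.32 with an estimated correlation). Ribosomal protein, G1/S and cholesterol lists passed upward without any gene called, and the heat shock list passed with HSP90AA1 (0.21), again not with an estimated correlation (adjusted p = 0.56 to 0.801 with an estimated correlation). The fatty acid list passed with Rep as a block only (adjusted p = 0.0889, and 3.62e-04 with the block). FOXO targets did not pass (1 of 23 rose, adjusted p = 0.864, median 0.00).

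In all, 336 genes changed, 187 higher and 149 lower, with 3 at least 2-fold lower, and with library size only 120 were higher and 222 lower. Rep as a block gave 1649 genes. Summed per Rep, edgeR called 0 genes, with 677 at an unadjusted p under 0.05 and 844 with Rep as a block, while DESeq2 on 30 libraries called 540 and voom with correlated sets 55. Single libraries moved this count. It was 164, 191 and 184 without DMSO Rep 1 (1), (2) or (3), 579 without DMSO Rep 2 (1), and 179 and 213 without PROTAC 1500 nM Rep 2 (2) or (3).

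To see what the higher dose of the PROTAC changed, SGI-1776-VHL-02 at 3750 nM was compared with DMSO. Nearly all genes of the ATF4 response rose, among them CHAC1, NUPR1, JDP2 and the cysteine-synthesis gene CBS. The mTORC1 inhibitor SESN2 and the cystine importer SLC7A11, members of the ATF4 list and of the p53 and NRF2 lists, rose too, and so did DDIT4 of the HIF list and the pro-apoptotic PMAIP1 of the BCL2 list. The p53, NRF2 and HIF lists did not hold (adjusted p = 0.115, 0.251 and 0.251 with an estimated correlation), and the BCL2 list did not pass. Where Rep was a block besides, the p53 list did pass with an estimated correlation. Mitosis genes fell, as with the inhibitor. Of 40 ribosomal protein genes 33 rose, of 35 respiratory chain genes 19 fell, and of 34 EMT and matrix genes 12 fell, SPARC among them, and 5 rose. None of these 3 lists held with an estimated correlation.

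Of the genes that also passed summed per Rep, the highest fold changes were those of CHAC1 (ENSG00000128965, chromosome 15, 40952962 to 40956519; 2.10 ± 0.16, adjusted p = 8.81e-12), ADM2 (ENSG00000128165, chromosome 22, 50481556 to 50486440; 2.08 ± 0.09, adjusted p = 1.07e-16), S100P (1.91 ± 0.09), NUPR1 (1.84 ± 0.11), CBS (1.73, with a near-identical copy) and JDP2 (1.65). The lowest were those of PPP1R1B (-1.91 ± 0.10, adjusted p = 4.26e-15), SERF1B (-1.91), DHRS2 (-1.60 ± 0.10), SPARC (ENSG00000113140, chromosome 5, 151661096 to 151687165; -1.51 ± 0.13), GBP4 (-1.34) and COL2A1 (-1.23). Of 30 ATF4 genes 28 rose and 1 fell (29 and 1 adjusted over the list alone, median 0.82, adjusted p = 1.3e-93), and of 30 mitosis genes 29 fell (29 adjusted over the list alone, median -0.32, adjusted p = 1.89e-34), including KIF20A (-0.56) and AURKA (-0.45). Both held with an estimated correlation (adjusted p = 2.71e-05 and 0.000825).

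Other lists passed at the preset correlation alone. Of 40 ribosomal protein genes 33 rose (36 adjusted over the list alone, adjusted p = 1.47e-17, but adjusted p = 0.115 with an estimated correlation), and of 35 respiratory chain genes 19 fell (22 fell and 1 rose adjusted over the list alone, adjusted p = 9.13e-09, but adjusted p = 0.115 with an estimated correlation). Of 25 cholesterol genes 17 rose (21 adjusted over the list alone, adjusted p = 7.32e-09, but adjusted p = 0.251 with an estimated correlation), and of 22 ER chaperones 10 rose (10 adjusted over the list alone, adjusted p = 8.74e-08, but adjusted p = 0.174 with an estimated correlation). Of 28 HIF targets 10 rose, including DDIT4 (1.58 ± 0.12) and STC2 (1.17 ± 0.07), and 2 fell (11 and 2 adjusted over the list alone, adjusted p = 0.00135, but adjusted p = 0.251 with an estimated correlation). Of 24 p53 targets 6 rose and 2 fell (7 and 2 adjusted over the list alone, adjusted p = 0.00877, but adjusted p = 0.115 with an estimated correlation), with SESN2 at 1.29 ± 0.09. HMOX1 (0.95) and SLC7A11 (1.12) were among 6 of 27 NRF2 targets that rose, and 3 fell (8 and 3 adjusted over the list alone, adjusted p = 0.00152, but adjusted p = 0.251 with an estimated correlation). Lysosome, autophagy, fatty acid, FOXO and metallothionein lists passed upward, and MYC, G1/S, EMT, proteasome, heat shock, glycolysis and interferon lists downward, none with an estimated correlation (adjusted p = 0.115 to 0.475 with an estimated correlation). With Rep as a block besides, p53, cholesterol and autophagy lists did (adjusted p = 0.00548, 0.00516 and 0.00516). The NF-kB, BCL2 and MAPK lists did not pass (adjusted p = 0.106, 0.0756 and 0.227), but the first 2 did without the 4 libraries of low mitochondrial share (adjusted p = 0.0310 and 0.0469). In these lists C3 (0.97), PMAIP1 (0.65) and KLF4 (0.67) rose and SPRY4 (-0.48) fell.

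In all, 3807 genes changed, 2011 higher and 1796 lower, with 77 at least 2-fold higher and 44 at least 2-fold lower, and 410 passed when libraries were summed per Rep. Between the doses of the PROTAC, 28 of 30 ATF4 genes were higher at 3750 than at 1500 nM and 1 was lower (28 and 1 adjusted over the list alone, median 0.59, adjusted p = 7.13e-69, and adjusted p = 0.000113 with an estimated correlation). Mitosis genes were lower in 29 of 30 cases (29 adjusted over the list alone, median -0.43, adjusted p = 1.63e-73, and adjusted p = 5.16e-06 with an estimated correlation). Of genes that also passed summed per Rep, those furthest higher were ADM2 (1.72 ± 0.09, adjusted p = 1.2e-14), S100P (1.54), CBS (1.53) and NUPR1 (1.47), and those furthest lower DHRS2 (-1.04 ± 0.10), PPP1R1B (-1.03 ± 0.10), ID3 (-0.66) and CENPE (-0.64). The MAPK and AhR lists did not differ between these doses (adjusted p = 0.446 each). The dose contrast held 3320 genes, 1616 higher and 1704 lower, with 136 summed per Rep and 5112 with Rep as a block.

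**Figure D4:**
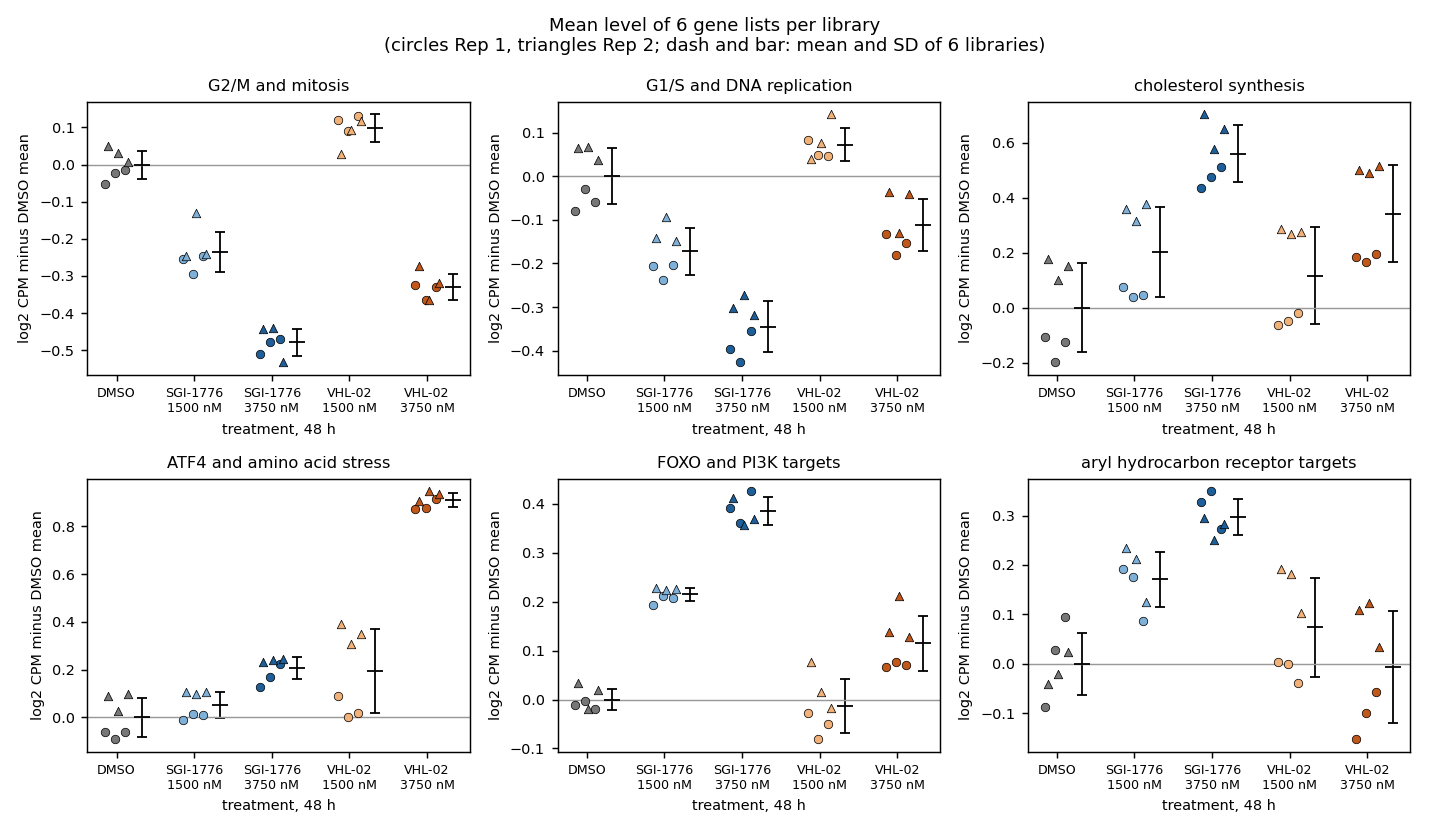
Mean log2 CPM less the DMSO mean of 6 gene lists in each library (vertical axis) by treatment for 48 h, with circles for Rep 1, triangles for Rep 2, and dash and bar for mean and SD of 6 libraries. The mitosis list averaged -0.24 and -0.48 with 1500 and 3750 nM SGI-1776 against 0.10 and -0.33 with the PROTAC, and the ATF4 list 0.05 and 0.21 against 0.19 and 0.91.

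To compare the 2 compounds at matched dose, the PROTAC was set against SGI-1776 at 1500 nM. Division genes were higher with the PROTAC, with CDC20, TOP2A and UBE2C, and so were genes of DNA replication and 23 of 32 MYC targets, a list that did not hold with an estimated correlation where Rep was a block (adjusted p = 0.0658). FOXO targets such as CCNG2 and IGF1R were lower. The growth factor genes EPGN and AREG were higher, and the matrix gene SPARC was lower.

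Among genes that passed here and again summed per Rep, those furthest higher with the PROTAC were EPGN (ENSG00000182585, chromosome 4, 74308473 to 74315307; 1.02 ± 0.09, adjusted p = 1.59e-09), KRT86 (0.87), POU2F2 (0.83), IL7R (0.80), AOX1 (0.75 ± 0.07) and KRT81 (0.75). KRT81 and KRT86 overlap in the annotation. Those furthest lower were FCGR2A (-1.26 ± 0.11, adjusted p = 5.45e-10), PPP1R1B (-1.26 ± 0.09, adjusted p = 5.11e-11), CLCN1 (-1.14), COL2A1 (-1.11), GJA5 (-1.11) and SPARC (-1.06). Of 30 mitosis genes 29 were higher (29 adjusted over the list alone, median 0.34, adjusted p = 1.01e-36), of 32 G1/S genes 29 (30 adjusted over the list alone, adjusted p = 1.21e-19) and of 32 MYC targets 23 (25 adjusted over the list alone, adjusted p = 9.85e-11). Of 23 FOXO targets 14 were lower and 1 higher (16 and 1 adjusted over the list alone, median -0.22, adjusted p = 2.4e-07). These 4 held with an estimated correlation (adjusted p = 0.000836, 0.049, 0.0214 and 0.00963), but MYC targets did not with Rep as a block besides (adjusted p = 0.0658). Proteasome genes were higher in 20 of 31 cases (26 adjusted over the list alone, adjusted p = 6.56e-09, but adjusted p = 0.39 with an estimated correlation) and ATF4 genes in 17 of 30 with 1 lower (17 and 1 adjusted over the list alone, median 0.20, adjusted p = 0.000402, but 0.113 without the 4 libraries of low mitochondrial share and adjusted p = 0.614 with an estimated correlation). Glycolysis, ribosomal, heat shock, ER chaperone, NRF2 and VHL ligase lists passed upward and the lysosome list downward, none with an estimated correlation (adjusted p = 0.39 to 0.623 with an estimated correlation). No difference passed for cholesterol synthesis (0 of 25 higher, 2 lower, median -0.08, adjusted p = 0.209, 0.0241 with Rep as a block and 0.0136 without the 4 libraries) or fatty acid synthesis (adjusted p = 0.498). In all, 4408 genes differed, 2527 higher and 1881 lower with the PROTAC, with 12 and 112 of them by at least 2-fold. Library size only gave 1614 higher and 2802 lower. Summed per Rep, 222 passed, and without all of Rep 1 the count was 2712.

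The same comparison was made at 3750 nM. The ATF4 response was higher with the PROTAC, with TRIB3, PSAT1 and CHAC1. HMOX1, DDIT4 and VEGFA were higher as well, but the HIF and NRF2 lists that hold them did not hold with an estimated correlation (adjusted p = 0.403 each). FOXO targets remained lower, with KLHL24 and BCL6. The AhR targets CYP1A1, ALDH3A1 and CYP1B1 were lower, and so were the prostate genes ACPP and FOLH1. Other members of both lists were higher, 2 and 3 of them, and neither list held (adjusted p = 0.227 each with an estimated correlation). Of 32 interferon genes 13 were lower, OAS1 and MX1 among them, and of 25 NF-kB genes 14 were higher, IL32 and LIF among them. Neither list held (adjusted p = 0.403 and 0.317 with an estimated correlation).

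Counting only genes that also passed summed per Rep, those furthest higher were ADM2 (1.69 ± 0.09, adjusted p = 4.38e-15), CHAC1 (1.53 ± 0.15), CBS (1.44), PI3 (1.43), KRT17 (1.38) and AOX1 (1.35 ± 0.07, adjusted p = 9.53e-16). Those furthest lower were PPP1R1B (-2.40 ± 0.10, adjusted p = 2.1e-17), COL2A1 (-2.11 ± 0.12, adjusted p = 2.8e-14), SPARC (-1.92), TCN1 (-1.80), TSPAN8 (-1.74) and FAM198B (-1.64). Of 30 ATF4 genes 25 were higher and 2 lower (25 and 2 adjusted over the list alone, median 0.65, adjusted p = 1.72e-42, and adjusted p = 0.0066 with an estimated correlation). Of 23 FOXO targets 16 were lower and 2 higher (16 and 2 adjusted over the list alone, median -0.21, adjusted p = 1.16e-06, and adjusted p = 0.0124 with an estimated correlation). Of 32 G1/S genes 27 were higher (28 adjusted over the list alone, adjusted p = 5.28e-11, but adjusted p = 0.227 with an estimated correlation), and of 30 mitosis genes 16 (17 adjusted over the list alone, median 0.14, adjusted p = 0.000105, but adjusted p = 0.384 with an estimated correlation). Of 25 NF-kB genes 14 were higher and 1 lower (16 and 2 adjusted over the list alone, adjusted p = 5.9e-06, but adjusted p = 0.317 with an estimated correlation), while of 32 interferon genes 13 were lower and ISG20 higher (14 and 1 adjusted over the list alone, adjusted p = 0.0014, but adjusted p = 0.403 with an estimated correlation). Of 9 AhR targets 4 were lower and 2 higher (4 and 2 adjusted over the list alone, adjusted p = 0.0021, but adjusted p = 0.227 with an estimated correlation), with CYP1A1 at -1.21 ± 0.12 and ALDH3A1 at -0.98 ± 0.07. Of 11 luminal markers 5 were lower and 3 higher (6 and 3 adjusted over the list alone, adjusted p = 0.0038, but adjusted p = 0.227 with an estimated correlation), with ACPP at -1.81 and FOLH1 at -1.54. Of 29 MAPK genes 14 were higher, JUN (0.56) among them, and 8 lower, SPRY4 (-0.80) among them (16 and 8 adjusted over the list alone, adjusted p = 0.0137, but adjusted p = 0.403 with an estimated correlation). Metallothioneins were higher in 3 of 5 cases, MT1X and MT2A among them (3 adjusted over the list alone, adjusted p = 0.0358, but 0.0751 with Rep as a block and adjusted p = 0.317 with an estimated correlation).

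Cholesterol and lysosome lists were lower, and MYC, HIF, NRF2, ER chaperone, ribosomal, proteasome and glycolysis lists higher, none with an estimated correlation (adjusted p = 0.317 to 0.553 with an estimated correlation). The respiratory chain list passed with Rep as a block only (adjusted p = 0.0541, and 0.0312 with the block). Autophagy (adjusted p = 0.304), the BCL2 family (adjusted p = 0.461, with BCL2A1 at 1.53), EMT (adjusted p = 0.184, median 0.13 and mean -0.00) and fatty acid synthesis (adjusted p = 0.469) did not differ. In all, 5451 genes differed, 3080 higher and 2371 lower with the PROTAC, with 98 and 215 of them by at least 2-fold, and 1401 passed summed per Rep. Library size only gave 2089 higher and 3364 lower.

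To test whether the compound difference depended on dose, the difference at 3750 nM was set against that at 1500 nM. ATF4 genes gained with the PROTAC at the higher dose beyond the gain with SGI-1776, CHAC1 among them. ADM2, not a member of that list, had the highest interaction of the genes named. Mitosis genes lost more of their level with the PROTAC between doses than with SGI-1776. CYP1A1 and PPP1R1B fell behind, and TNFAIP3, a brake on NF-kB signalling, and the elastase inhibitor PI3 moved ahead.

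Of genes that also passed summed per Rep with Rep as a block, the interaction was highest for ADM2 (1.42 ± 0.13, adjusted p = 2.45e-08), TNFAIP3 (1.09 ± 0.25), CHAC1 (1.07 ± 0.22) and PI3 (1.02 ± 0.26), and lowest for PPP1R1B (-1.14 ± 0.13, adjusted p = 1.68e-06), CYP1A1 (-1.02 ± 0.16), COL2A1 (-0.99 ± 0.17) and ALPP (-0.95 ± 0.09, adjusted p = 7.06e-08). Of 30 ATF4 genes 19 rose (24 rose and 1 fell adjusted over the list alone, median 0.53, adjusted p = 1.17e-67, and adjusted p = 0.000302 with an estimated correlation), and of 30 mitosis genes 7 fell (19 adjusted over the list alone, median -0.18, adjusted p = 6.38e-20, and adjusted p = 0.0171 with an estimated correlation). In all, 468 genes passed, 290 upward and 178 downward, and 1086 passed with Rep as a block. Summed per Rep, edgeR called 0 genes, with 623 at an unadjusted p under 0.05 and 469 with Rep as a block. On 30 libraries DESeq2 called 596 and voom with correlated sets 99. Without all of Rep 1 the count was 269.

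Some lists passed in none of the 9 comparisons. The 13 mitochondrially encoded genes did not change against DMSO (adjusted p = 0.243 to 0.874), with 0 of 13 called in each. Neuroendocrine markers (3 tested, adjusted p = 0.437 to 0.892), leukocyte markers (3 tested, adjusted p = 0.729 to 0.921) and fibroblast and endothelial markers (7 tested, adjusted p = 0.347 to 0.882) did not pass against DMSO either, although the collagen gene COL3A1 of the last list rose with 1500 nM SGI-1776 (0.35) and fell with 3750 nM PROTAC (-0.87). In no passing list did median, mean and test differ in sign, and none of the 152 passing medians changed sign with RLE factors or library size only.

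To compare the responses as wholes, fold changes were correlated across all 17499 genes. The genes changed by both doses of SGI-1776 moved in the same direction without exception, 898 higher and 1297 lower. Genes changed by both compounds at 1500 nM moved mostly in opposite directions, 94 of 124, where 22.2 opposite genes were expected of independent calls. At 3750 nM 933 were higher and 1035 lower with both compounds and 399 moved in opposite directions. Contrasts that share the DMSO libraries share calls of 1 direction without a common response, so the counts of genes moving together do not show one. Sharing these libraries works against opposite calls, so it does not account for the 94 opposite genes at 1500 nM. For SGI-1776 the correlation between doses was 0.780 (Spearman 0.783), against 0.504 in simulated unchanged groups with the same DMSO libraries, and for the PROTAC 0.486 (Spearman 0.425), against 0.506. Between compounds it was 0.111 at 1500 nM (Spearman 0.0251, simulated 0.514) and 0.370 at 3750 nM (Spearman 0.400, simulated 0.498). With the DMSO libraries split between the contrasts, these 4 correlations were 0.452, 0.170, -0.163 and 0.168. No such split balances the Reps, so the contrasts carry opposite Rep imbalances, which lower these values by construction. The negative value therefore does not show opposite responses. The covariance was 0.0513 for SGI-1776 against 0.0155 simulated, 0.0268 for the PROTAC against 0.0153, 0.00481 between compounds at 1500 nM against 0.0155, and 0.0310 at 3750 nM against 0.0154. Changes between doses, which share no library, correlated at 0.336 (Spearman 0.406, simulated 0.00596), with 420 genes higher and 555 lower for both compounds and 28 opposite. Compound differences at the 2 doses shared 1799 genes higher and 1284 lower with the PROTAC, and 15 were opposite.

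By size, the root mean square log2 fold change against DMSO was 0.210 and 0.315 for 1500 and 3750 nM SGI-1776 and 0.210 and 0.267 for the PROTAC, against 0.173 to 0.177 in simulated unchanged groups. Libraries lay 0.403 ± 0.0371 (SD, n = 6) from the DMSO mean with 3750 nM SGI-1776 and 0.341 ± 0.0134 with 3750 nM PROTAC. The PROTAC libraries lay nearer to DMSO by this measure (difference -0.0613, exact permutation p = 0.00433, adjusted p = 0.0173). Libraries with 3750 nM SGI-1776 lay farther than those with 1500 nM (difference 0.0884, exact permutation p = 0.00216, adjusted p = 0.0173, the smallest these arrangements give). Against DMSO libraries, which lay 0.310 ± 0.0724 from the mean of the others, 3750 nM SGI-1776 missed the threshold (difference 0.0926, exact permutation p = 0.0281, adjusted p = 0.0750), and measured within Rep it passed (adjusted p = 0.0231). The PROTAC at 3750 nM missed it too (difference 0.0312, exact permutation p = 0.346, adjusted p = 0.693, and within Rep p = 0.0671, adjusted p = 0.134), as did SGI-1776 and the PROTAC at 1500 nM (0.314 ± 0.0224 and 0.334 ± 0.0876, adjusted p = 0.935 and 0.921). The library DMSO Rep 2 (1), at 0.455, raised the DMSO mean. Without Rep 2 all 4 treatments lay farther than DMSO, by 0.0289, 0.131, 0.0424 and 0.0806 in the order of the groups, each at the smallest p that 3 against 3 libraries can give (exact permutation p = 0.1). Without Rep 1 the differences were -0.0362, 0.0565, -0.0140 and 0.00488.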

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

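The tests of mitochondrial reads and of depth for the difference between Reps were chosen after that difference had been seen, as was leaving out the 4 libraries with a low mitochondrial share. Libraries far from the others of their group were sought in 65 groups of 6 values, and 4 were found, where chance gives about 1 in 20. PROTAC 1500 nM Rep 2 (3) had 48.97 M counts, against 25594649 to 34304478 in the other libraries of its group. DMSO Rep 2 (1) lay 0.455 from the mean of the other DMSO libraries, which lay at 0.258 to 0.297. The mitosis list stood at -0.13 in SGI-1776 1500 nM Rep 2 (2) and at -0.30 to -0.24 in the other 5. PIM1 stood at 47.0 CPM in SGI-1776 3750 nM Rep 1 (1) and at no more than 44.4 in the other 5.

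By the test of the interaction, the difference between compounds changed with dose for 468 genes, and for 596 by DESeq2 on 30 libraries. Summed per Rep, edgeR called 0 genes (623 at an unadjusted p under 0.05), and 469 with Rep as a block. The interaction passed for 16 lists. Of these, 14 did not hold with an estimated correlation and 5 not without the 4 libraries of low mitochondrial share. CHAC1 of the ATF4 list and ADM2, which is not a member, were higher with the PROTAC at 3750 nM in either Rep. At 1500 nM the difference of CHAC1 lay mostly in Rep 2 (0.69, and 0.10 in Rep 1), and the ATF4 list did not pass without the 4 libraries of low mitochondrial share (adjusted p = 0.113). The interaction of ADM2 was 1.70 in Rep 1 and 1.16 in Rep 2, that of CHAC1 1.58 and 0.71. ADM2 parted the compounds by 0.27 at 1500 and 1.69 at 3750 nM (interaction 1.42), CHAC1 by 0.46 and 1.53 (1.07), TNFAIP3 by 0.17 at 1500 nM (1.09) and PI3 by 0.42 and 1.43 (1.02). PPP1R1B parted them by -1.26 and -2.40 (interaction -1.14), CYP1A1 by -0.19 and -1.21 (-1.02), COL2A1 by -1.11 and -2.11 (-0.99), and ALPP by 0.17 and -0.78 (-0.95). For VHL the differences were -0.04 and 0.16 (interaction 0.19, adjusted p = 0.0485).

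Among lists, the ATF4 genes (median interaction 0.53) and the mitosis genes (-0.18) passed with an estimated correlation too. At the preset correlation alone, HIF targets (median 0.11, adjusted p = 0.000171), metallothioneins (0.33, adjusted p = 0.00384), NF-kB genes (0.18, adjusted p = 8.58e-07), ER chaperones (0.0676, adjusted p = 0.00178) and p53 targets (0.0283, adjusted p = 0.0302) moved upward. Interferon genes (-0.26, adjusted p = 6.63e-09), respiratory chain genes (-0.11, adjusted p = 4.34e-09), cholesterol genes (-0.13, adjusted p = 0.000855), luminal markers (-0.13, adjusted p = 0.0302), lysosomal genes (-0.0501, adjusted p = 0.0341), proteasome genes (-0.0501, adjusted p = 0.018), heat shock genes (-0.0452, adjusted p = 0.0166), MYC targets (-0.0389, adjusted p = 0.0108) and AhR targets (-0.0291, adjusted p = 0.00123) moved downward. None of these 14 held (adjusted p = 0.148 to 0.664 with an estimated correlation). Without the 4 libraries of low mitochondrial share, the calls ended for cholesterol (median -0.00954, adjusted p = 0.495), lysosomal (-0.0227, adjusted p = 0.307), proteasome (-0.0185, adjusted p = 0.503), luminal (-0.0719, adjusted p = 0.307) and heat shock genes (-0.0506, adjusted p = 0.0536), and the median of the AhR targets turned to 0.0221.

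To ask whether chance gives such counts, the libraries of the groups compared were split in 100 ways, the real one included. For SGI-1776 against DMSO at 1500 nM, 2 of the 100 gave as many genes as the real 2076, the other being the split by Rep (5353 genes). At 3750 nM only the real split did (1 of 100, 5773 genes, next 1545 by Rep). For the PROTAC at 1500 nM 3 of 100 did (125 genes, 5233 by Rep) and at 3750 nM 1 of 100 (3752 genes, 2791 by Rep). The 3 were the real split, the split by Rep and a random split with Reps unbalanced, which gave 445 genes. Between compounds it was 2 of 100 at 1500 nM (3655 genes, 4261 by Rep) and 1 of 100 at 3750 nM (5092 genes, 1140 by Rep). Between doses it was 4 of 100 for SGI-1776 (1085 genes, 4340 by Rep) and 2 of 100 for the PROTAC (3075 genes, 3315 by Rep), and for the interaction 1 of 100 (406 genes, next 1). The 4 for SGI-1776 also included random splits with Reps unbalanced.

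The Rep-following splits show a structure of the samples. Splits with Reps balanced gave at most 21 genes (SGI-1776 3750 nM), 1 (either dose of PROTAC) and 0 (the other 6 contrasts). With Rep as a block only the real split was as large (1 of 100) in all 9 contrasts. In the contrast order of the report these gave 4209 genes against a next highest of 69, 7135 against 0, 1267 against 691, 5278 against 1196, 6284 against 0, 6370 against 566, 2496 against 115, 5022 against 818, and 1034 against 766. A share of 1 of 100 is the smallest that 100 splits can give. It makes chance between libraries unlikely in any 1 contrast but does not exclude it over all 9. Chance between cultures was not tested, since the labels do not say which libraries share a culture.

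Mitochondrially encoded genes were all lower in Rep 2, MT-CO1 by -1.47, and 9329 genes differed between Reps (4759 higher, 4570 lower in Rep 2). GC content and length explained 8.98% of the variance of this difference across genes (upper bound 9.80%), so they were not the whole cause. Fewer mitochondrial reads alone would leave nuclear genes level, but 53.2% of them were called. Depth explained 2.01% of the first axis (upper bound 25.2%). A different culture day, RNA handling or library batch stays open, since the labels name none, and no biological explanation was tested.

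The ATF4 genes were higher with the PROTAC than with SGI-1776 at 3750 nM. The lower of the medians in Rep 1 and Rep 2 was 0.65 (spread 0.0836), so the difference was present in either Rep. The spread here and below is the SD of the median when list members are drawn again. It measures variation between genes and not between libraries or cultures. Each group holds 3 libraries of each Rep, so a plain shift between Reps cancels from this contrast. None of 10000 random lists matched on GC content, length and expression reached the median of all libraries (percentile 100, highest 0.16). Their genes were drawn separately, so they lack the shared movement of a real list. With 1 of 12 libraries left out the lowest median was 0.63. A response to the PROTAC itself may be the source, as a hypothesis. Whether degradation, the VHL ligand or another part of the molecule is responsible was not tested, since the design holds no PROTAC that cannot bind VHL.

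The mitosis list was slightly higher with 1500 nM PROTAC than with DMSO, with 4 of 30 genes called, and did not hold with an estimated correlation (adjusted p = 0.264), so the rise is not settled. Without the 4 libraries of low mitochondrial share the median was 0.13 (spread 0.0112). None of 10000 matched random lists reached the median of all libraries (percentile 100, highest 0.0926). Genes of these lists were drawn separately and lack the shared movement of a real list, so this does not settle the rise either. The medians of 0.16 in Rep 1 and 0.0522 in Rep 2 (spread 0.0130) leave open how much of the rise belongs to Rep 1. A small rise in dividing cells may lie behind it, as a hypothesis that was not tested.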

How the results depend on the processing

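Robust edgeR, the mitochondrial covariate with and without Rep, the estimated correlation with Rep as a replicate block, and leaving out the 4 libraries of low mitochondrial share were chosen after the data were seen. All 9 counts of genes stayed within 1.5 times their value with RLE factors, library size only, a mean of at least 1 CPM, the bracketed number as a replicate block and robust edgeR.

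For SGI-1776 1500 nM against DMSO the count was 1273 with no filter, 3772 with Rep as a replicate block, 0 summed per Rep, 3924 summed per bracketed number, 541 with voom, 19 at 2-fold or more, 31 with glmTreat, 3938 with the mitochondrial covariate and 4493 with covariate and Rep. For 3750 nM it was 1742 summed per Rep, 3601 with voom, 220 at 2-fold or more and 1168 with glmTreat. For PROTAC 1500 nM it was 540 with DESeq2, 167 with no filter, 1649 with Rep as a replicate block, 0 summed per Rep, 844 summed per Rep with the block, 2358 summed per bracketed number, 55 with voom, 125 fitted on the groups compared, 3 at 2-fold or more, 12 with glmTreat, 212 without the 4 libraries, 964 with the covariate and 1521 with covariate and Rep. For 3750 nM it was 410 summed per Rep, 1693 with voom, 121 at 2-fold or more, 442 with glmTreat and 6008 with covariate and Rep.

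Between compounds at 1500 nM it was 222 summed per Rep, 1929 with voom, 124 at 2-fold or more and 378 with glmTreat, and at 3750 nM 1401, 2871, 313 and 1159. Between doses of SGI-1776 it was 907 with no filter, 3028 with Rep as a replicate block, 0 summed per Rep, 3231 summed per bracketed number, 327 with voom, 9 at 2-fold or more, 23 with glmTreat, 2995 with the covariate and 3584 with covariate and Rep. Between doses of the PROTAC it was 5112 with Rep as a replicate block, 136 summed per Rep, 5412 summed per bracketed number, 1336 with voom, 60 at 2-fold or more and 239 with glmTreat. For the interaction it was 229 with no filter, 1086 with Rep as a replicate block, 0 summed per Rep, 1103 summed per bracketed number, 99 with voom, 22 at 2-fold or more, 52 with glmTreat, 966 with the covariate and 1158 with covariate and Rep. Summing left 2 samples per group, fitted without the pairing by Rep. The same sums with Rep as a block called 2303 genes for SGI-1776 1500 nM, 1654 between its doses and 469 for the interaction. In the simulation 10.4% of the calls of that blocked fit were unchanged genes. The number of samples alone therefore does not account for the loss. The 2-fold and glmTreat thresholds ask for more change. Elsewhere the cause was not tested.

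With libraries left out, counts ran from 1097 to 2178 for SGI-1776 1500 nM, 164 to 607 for PROTAC 1500 nM, 2712 to 4611 between compounds at 1500 nM and 269 to 469 for the interaction. Without all of Rep 1 the PROTAC 1500 nM count was 217, and without all of Rep 2 it was 607.

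The correlation between doses of SGI-1776 was 0.452 with DMSO split, 0.928 over genes called in either, and 0.675 to 0.722 without 1 Rep. Between doses of the PROTAC it was 0.170 with DMSO split and 0.693 over genes called in either. Between compounds at 1500 nM it was -0.163 with DMSO split and -0.0860 over genes called in either, where the sign turned, and 0.127 to 0.370 without 1 Rep. At 3750 nM it was 0.168 with DMSO split and 0.318 to 0.490 without 1 Rep. Between the dose contrasts it was 0.354 with a prior count of 2, 0.565 over genes called in either and 0.249 to 0.250 without 1 Rep. Sharing the DMSO libraries raises a correlation by construction. Splitting them lowers a correlation, because no even split of the DMSO libraries balances the Reps. The contrasts then carry opposite Rep imbalances, and 9329 genes differed between Reps. How far this lowered the values with DMSO split was not measured. The turn of sign with DMSO split therefore does not show opposite responses.

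The root mean square change at a mean of at least 1 CPM was 0.167 and 0.273 for SGI-1776 and 0.153 and 0.222 for the PROTAC, the cause of which was not tested, and without 1 Rep it was 0.249 to 0.269, 0.346 to 0.363, 0.259 to 0.270 and 0.314 to 0.315. The distance of SGI-1776 3750 nM from DMSO passed at a mean of at least 1 CPM (difference 0.112, exact permutation adjusted p = 0.0346) and within Rep (0.0939, exact permutation adjusted p = 0.0231). With 1 Rep left out no distance could pass, since the smallest p was 0.1.

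Over the 9 contrasts, 152 tests of the 32 lists passed. Of these, the estimated correlation ended 123 (105 with Rep as a replicate block), fry 18 and a mean of at least 1 CPM 10. Rep as a replicate block ended 5, RLE factors 2, summing per Rep 5 and leaving out the 4 libraries 15. By the direction of a test that passed, 1 list turned, and it was not among the 152. It was that of mitochondrially encoded genes in the interaction without the 4 libraries (adjusted p = 0.00659, median -0.50, against a median of 0.21 and no call with all libraries, and adjusted p = 0.0211 with Rep as a replicate block). Medians can turn besides, as that of the AhR targets did in the interaction (0.0221), where the test stayed downward (adjusted p = 0.0321). Those 4 libraries have the lowest mitochondrial share.

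Without the 4 libraries these calls ended: VHL ligase, respiratory chain and heat shock with SGI-1776 1500 nM (adjusted p = 0.165, 0.0907 and 0.112), cholesterol with PROTAC 1500 nM (0.196), VHL ligase, NRF2, ATF4 and ER chaperones between compounds at 1500 nM (0.108, 0.202, 0.113 and 0.309), PIM kinases between doses of SGI-1776 (0.0866), interferon between doses of the PROTAC (0.216), and cholesterol, lysosome, proteasome, heat shock and luminal lists in the interaction (0.495, 0.307, 0.503, 0.0536 and 0.307). Gained were MYC targets with PROTAC 1500 nM (0.00112), NF-kB and BCL2 with 3750 nM (0.0310 and 0.0469), cholesterol, autophagy, AhR and luminal lists between compounds at 1500 nM (0.0136, 0.0162, 0.0284 and 0.0162), respiratory chain between doses of SGI-1776 (0.0323), NRF2 between doses of the PROTAC (0.0154), and NRF2, BCL2 and MAPK in the interaction (0.00204, 0.00842 and 0.0192). With Rep as a replicate block the calls of interferon (0.0319, 0.0778 with the block) and metallothioneins (0.0379, 0.0543 with the block) between doses of the PROTAC ended. The other changes with the block are given beside their results, and the cause was not tested.

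Of 399 calls of named genes, none turned. DESeq2 ended 0 of 396, Rep as a replicate block 0, library size only 9, RLE factors 2, summing per Rep 143, summing per Rep with the block 0, and leaving out all of Rep 1 or Rep 2 33 and 41. At depths of 22520292 to 48968707 counts, filterByExpr kept 17499 of 58735 genes, and 20677 had no count in any library.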

Other observations

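The list of histone genes was chosen after the genes with the highest changes had been seen, so a test of it on the same data shows nothing and only counts and medians are given. Those histone genes that passed moved mostly in opposite directions with the 2 compounds. Replication-dependent histone mRNAs lack a poly-A tail in dividing cells, so poly-A selection normally leaves few of them.

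Of 42 histone genes, 15 rose and 0 fell with 1500 nM SGI-1776 (median 0.27), and 26 rose and 2 fell with 3750 nM (median 0.63). With the PROTAC 10 fell and 0 rose at 1500 nM (median -0.30), and 14 fell and 1 rose at 3750 nM (median -0.35). Between compounds 27 were lower and 1 higher with the PROTAC at 1500 nM (median -0.60), and 34 lower and 1 higher at 3750 nM (median -0.96). Between doses 15 were higher with SGI-1776 (median 0.36), and 5 higher and 4 lower with the PROTAC, and in the interaction 5 were lower (median -0.32). The median had the same sign in Rep 1 and Rep 2 in all of these but the doses of the PROTAC. The cause was not tested, and the share of histone transcripts with a poly-A tail was not measured here.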
